A study of Homo sapiens with 15 samples.

How the data were processed

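The samples were libraries of messenger RNA from the small cell lung cancer line NCI-H69. Of 15 samples in the labels, the 9 of H69 (3 each with DMSO, CS2 and FB23-2) had columns in the table used here, matched to the labels by name, and the 6 of H82 were not analysed here. A column named FB23 was taken as FB23-2, the only treatment of H69 in the labels with that start. Total RNA was isolated with TRIzol and libraries were made with the Hieff NGS Ultima Dual-mode mRNA kit, per the labels' protocols. The authors deposited whole-number read counts per gene, not normalized, which differ in total between libraries. The genome build is hg38, per the submitters' processing notes. The aligner, the counting tool, its annotation and its strand setting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies may therefore be split or mixed in ways that the counts do not show.

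The table held 62754 Ensembl gene IDs, of which 42343 could be paired with a symbol. Coordinates, spans and exon overlaps came from GENCODE release 29 on GRCh38, which holds 58261 of the IDs and lacks 4493. For each named gene the share of exon bases overlapped by another gene and the share of 50-base windows of its transcripts found in other genes were computed in Python 3.11.15.

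Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 19781 genes holding from 99.9% to 99.92% of the counts of each library, and libraries were scaled by TMM. All 9 libraries entered a single quasi-likelihood fit with robust estimation (glmQLFit, glmQLFTest), with group means and no covariate, because the groups are of a single cell line and so share an estimate of the spread. The biological coefficient of variation was 0.101. The contrasts were CS2 minus DMSO, FB23-2 minus DMSO and FB23-2 minus CS2, and the last is also the test of the difference between the effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE of a log2 fold change was taken as its size divided by the square root of its F statistic. Intervals and limits from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

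Before the data were examined, 37 gene lists were fixed: pathways, stress responses, small cell lung cancer subtype markers and markers of other cell types. Of these, 35 had at least 5 tested members and were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Some genes belong to more than one list. Genes named in the text follow a rule fixed at the same time. It takes 14 genes of m6A, neuroendocrine identity and the compounds' reported targets in every comparison. It adds the 8 largest increases and 8 largest decreases for each compound against DMSO, and 6 and 6 between the compounds. These are called genes with a mean of at least 10 CPM in a group, groups whose libraries do not overlap and a symbol that is not a clone, LINC or pseudogene name. It also takes up to 4 members of each list that passed and up to 2 of each that did not, the 5 genes called in opposite directions by the compounds and the 6 called in the same direction with the largest effects. Only part of these genes is printed, and results for some of them are not reported here.

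Pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom at least 4.21), so none was counted as a library deposited more than once. This check does not show that the libraries came from separate cultures, for which the series' wording is the only source used here. The p-values measure the spread between libraries that the series calls biological replicates.

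The tests were run on simulated data with known answers, 20 draws of counts with the real means and library sizes. With dispersions taken from their trend, false calls averaged 4.55% of the calls for CS2, 4.53% for FB23-2 and 4.66% between the compounds. With dispersions that vary by gene they averaged 7.62%, 7.28% and 6.31%, above the nominal level, so the test was somewhat liberal in these draws. Few genes were changed in the draws and many were called in the data. These averages therefore do not give the share of false calls in the data. In the latter simulations, over a mean of 19295 genes, 11.8% of genes changed by 1.25-fold, 54.4% by 1.5-fold, 71.7% by 2-fold and 93.3% by 4-fold were recovered for CS2. For FB23-2 the shares were 12.8%, 52.9%, 72% and 94%, and between the compounds 17.7%, 55.3%, 73.2% and 95.3%. Camera called every changed list (20, 20 and 40) and 0 of the unchanged lists (680, 680 and 660), lists whose simulated genes vary independently, with the preset correlation.

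Alternatives fixed in advance were RLE factors, library size alone, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.01, glmTreat against a 1.5-fold change, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after seeing the data were the removal of mitochondrial genes, a correction of each library for GC content and gene span through offsets (values for 95.6% of the tested genes), and list counts without FB23-2 replicate 2 or DMSO replicate 1. Shared effects of the compounds were set beside 50 simulations in which all 9 libraries were drawn from a single mean per gene. Figures were drawn with matplotlib 3.10.9.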

Results

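RNA was sequenced from NCI-H69, an established human cell line of classic small cell lung cancer, to see which transcripts change when FTO, an enzyme that removes the m6A methyl mark from RNA, is inhibited. The cells had received CS2 or FB23-2, which the series names as FTO inhibitors, or the solvent DMSO as control. CS2 is also known as brequinar, an inhibitor of DHODH, an enzyme of pyrimidine synthesis. Each group had 3 libraries, which the series calls biological replicates. Doses and treatment times were not given in the sources used here, so the compounds are compared as labelled and not at a known matched dose. Total counts per library ranged from 31404658 to 45022633 with DMSO, from 29916267 to 33663742 with CS2 and from 32352835 to 43957839 with FB23-2. A count of 3 corresponded to between 0.0666 and 0.101 CPM, the read count scaled to library size, and 19781 genes were tested. The 6 libraries of a further line, H82, were not analysed here.

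The libraries separated by treatment. Correlations of log2 CPM lay between 0.9877 and 0.9928 for pairs of 1 group and between 0.9392 and 0.967 for pairs of different groups. The first principal component held 49.4% of the variance and the second 29.8%. Genes of the mitochondrial genome took 5.46% ± 0.26 (SD, n = 3) of the counts with DMSO, 8.22% ± 0.88 with CS2 and 8.24% ± 2.4 with FB23-2. FB23-2 replicate 2 stood apart at 10.97%, against 6.83% and 6.91% in the other FB23-2 libraries. The mitochondrial ribosomal RNAs alone took 0.983% ± 0.075 with DMSO, 4.11% ± 0.52 with CS2 and 2.42% ± 0.85 with FB23-2. Gene values are means ± SD of CPM over 3 libraries. Each log2 fold change has its standard error (SE) and an adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the genes named, LDHB (33.4%), CCDC154 (23.5%), RARA (17.9%), USP2 (17.5%), RPL13A (17.3%), PLK1 (12.5%), NBAT1 (11.7%) and ALKBH5 (11.2%) share the given part of their exon bases with other genes. LDHB (58.5%), RNASEH2A (40.2%), RPL13A (16.5%) and AKR1C3 (12.1%) share the given part of their 50-base windows with other genes. The counts of these genes are uncertain. Gene lists fixed before the data were examined were tested with camera. The count adjusted over the list alone is printed where it differed from the count over all genes, and otherwise the counts were equal. Of the 35 lists tested, 16 passed camera with CS2, 16 with FB23-2 and 17 between the compounds, and 0 passed in any comparison when the correlation between genes was estimated from the data.

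The first comparison asked which transcripts differ between CS2 and DMSO. With CS2, 18 of 26 genes of G1/S and DNA replication rose (2 fell), as did 15 of 24 p53 targets (2 fell), 15 of 21 interferon-stimulated genes (3 fell) and 10 of 14 antigen presentation genes (0 fell). In contrast, 33 of 53 ribosomal protein genes fell (1 rose), as did 13 of 20 replication-dependent histone genes (0 rose) and 7 of 13 mitochondrial mRNAs (2 rose). Each of these lists passed camera and lost its call with an estimated correlation (adjusted p = 0.136 to 0.655 with an estimated correlation). TK1, the thymidine salvage kinase, rose 4.08-fold to 159 ± 8.3 CPM from 38.9 ± 0.9 (log2 fold change 2.03 ± 0.11 SE, adjusted p = 2.11e-11). MT-CYB, the mitochondrially encoded cytochrome b, fell from 2810 ± 290 to 663 ± 42 CPM (log2 fold change -2.09 ± 0.10, adjusted p = 7.58e-12). In all, 9829 genes passed, 4815 higher and 5014 lower, and 3143 of them differed by more than 2-fold, 1250 higher and 1893 lower.

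FTO itself (ENSG00000140718, chromosome 16, 53701692 to 54158512, plus strand, GRCh38) was lower with CS2, at 39.8 ± 0.31 CPM against 56.9 ± 1.6, a log2 fold change of -0.52 ± 0.09 (adjusted p = 6.74e-05). FTO spans 456.8 kb, and when each library was corrected for the GC content and span of its genes, an alternative chosen after seeing the data, its direction turned to 0.38 (adjusted p = 1.46e-04; range over all alternatives 4.48e-07 to 1). This correction also takes out any effect of CS2 that follows span, so 0.38 is relative to genes of like span and GC content. DHODH, the known target of brequinar, fell by 0.68 on the log2 scale (± 0.12, adjusted p = 1.45e-04), from 12.6 ± 0.89 to 7.87 ± 0.6 CPM. MYCN, a proto-oncogene transcription factor, fell from 1230 ± 35 to 862 ± 120 CPM (log2 fold change -0.51 ± 0.10, adjusted p = 2.41e-04). CEBPA, a myeloid transcription factor, rose by 2.20 ± 0.46 (adjusted p = 5.42e-04) but only from 0.197 to 0.924 CPM, and 43.4% of its exon bases overlap other genes. ALKBH5, another m6A demethylase, was higher by 0.28 ± 0.09 (adjusted p = 0.0129), a call lost without DMSO replicate 2 (log2 fold change 0.21) or DMSO replicate 3 (0.26) and with the correction for GC content and span (0.13). The glycolytic enzyme PFKP was lower by a log2 change of -0.31 ± 0.09 (adjusted p = 0.0109), a call lost without CS2 replicate 2 (-0.23) or CS2 replicate 3 (-0.24). METTL3 (0.15), METTL14 (0.15), NEUROD1 (-0.36), MYC (0.43), RARA (0.01) and LDHB (-0.30) did not pass. ASB2 had 6 counts over all 9 libraries and was not tested.

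**Figure D1:**
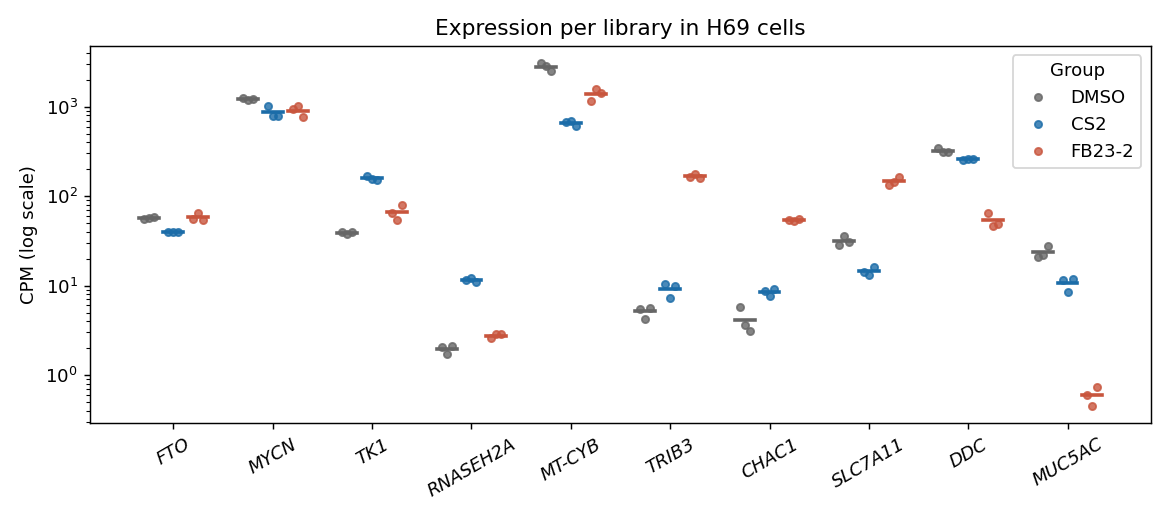
Expression of 10 genes in each library of H69 cells, in CPM on a log axis. Points are single libraries, 3 per group, and bars are group means. TRIB3 averaged 5.16 CPM with DMSO, 9.16 with CS2 and 166 with FB23-2, whereas TK1 averaged 38.9, 159 and 66.

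Among the largest increases with CS2 were DYRK4, a dual-specificity kinase, which rose 11.8-fold to 124 ± 21 CPM, and CABYR, a calcium-binding protein known from sperm, which rose 6.72-fold to 183 ± 32 CPM. CTSV, a lysosomal cysteine protease, rose 5.29-fold, USP2, a deubiquitinase, 4.84-fold, and RND1, a small GTPase, 7.09-fold. MIR7-3HG, a microRNA host gene, rose 5.18-fold. RNASEH2A, the catalytic subunit of RNase H2, rose 5.8-fold, with 30.8% of its exon bases shared with THSD8. The small mitochondrial ribosomal RNA MT-RNR1 rose 4.72-fold to 5160 ± 740 CPM. The adjusted p of these genes ranged up to 2.69e-06, that of MT-RNR1. The largest decreases were in HS6ST3, a heparan sulfate sulfotransferase (12.2-fold), GPC6, a glypican (10.8-fold), UBOX5, a ubiquitin ligase (10.6-fold), NEGR1, a neuronal adhesion protein (9.9-fold), THSD7A (9.57-fold), NLGN1, a synaptic adhesion protein (8.79-fold), MACROD2 (8.35-fold) and NKAIN2 (8.23-fold). Their adjusted p ranged up to 3.34e-08, that of GPC6. UBOX5 spans 52.6 kb, and the other 7 span from 461.8 kb (THSD7A) to 2057.8 kb (MACROD2).

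Genes with long spans were lower with CS2 as a class, a grouping chosen after the values were seen. Of 230 protein-coding genes spanning over 500 kb, 203 (88.3%) were lower and 5 higher by edgeR, with a median log2 fold change of -1.40. Of 864 genes spanning 200 to 500 kb, the class that holds FTO, 600 (69.4%) were lower and 44 higher, with a median of -0.57. Of 2269 genes spanning up to 10 kb, 432 (19%) were lower and 813 higher, with a median of 0.15. With FB23-2 the medians of these classes were -0.24, -0.04 and -0.15. Of the genes over 500 kb, 108 (47%) were lower with FB23-2 and 35 higher. For 200 to 500 kb, 298 (34.5%) were lower and 252 higher, and for up to 10 kb 887 (39.1%) were lower and 464 higher.

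**Figure D2:**
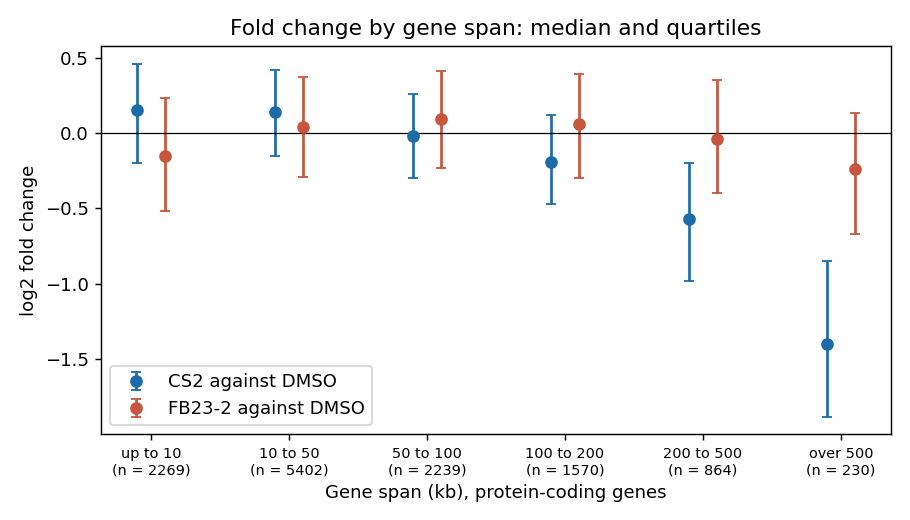
Log2 fold change against gene span in kb for protein-coding genes, with CS2 or FB23-2 against DMSO. Points are medians and bars run from the lower to the upper quartile of the genes in each class. The median with CS2 went from 0.15 in genes up to 10 kb to -1.40 in genes over 500 kb.

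Of 26 genes of G1/S and DNA replication, 18 rose and 2 fell (camera adjusted p = 1.42e-05, adjusted p = 0.221 with an estimated correlation). The replication factors GINS2 (log2 fold change 0.95 ± 0.08) and MCM10 (0.88 ± 0.08), the transcription factor E2F1 (0.76 ± 0.08) and the checkpoint adaptor CLSPN (0.81 ± 0.08) rose. Of 22 genes of homologous recombination, 15 rose and 1 fell (camera adjusted p = 2.29e-04, adjusted p = 0.136 with an estimated correlation), among them the nuclease EXO1 (1.01 ± 0.09) and the tumour suppressor BRCA1 (0.62 ± 0.07). Of 20 genes of pyrimidine and deoxynucleotide synthesis, 11 rose and 4 fell (camera adjusted p = 0.00887, adjusted p = 0.136 with an estimated correlation), including the nucleoside transporter SLC29A1 (1.15 ± 0.08) and the uridine-cytidine kinase UCK1 (0.64 ± 0.08). Of 24 genes of G2/M and mitosis, 15 fell and 4 rose (camera adjusted p = 0.0095, adjusted p = 0.387 with an estimated correlation), led by the mitotic kinase PLK1 (-0.80 ± 0.07). Of 20 replication-dependent histone genes, 13 fell and 0 rose (camera adjusted p = 1.03e-04, adjusted p = 0.136 with an estimated correlation), with H2BC11 at -2.47 ± 0.14 and H2AC6 at -1.91 ± 0.13. How fully histone transcripts are captured in libraries of messenger RNA was not measured. In every comparison, their counts may therefore not follow the histone mRNA level of the cells.

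Of 24 p53 target genes, 15 rose and 2 fell (camera adjusted p = 0.00125, adjusted p = 0.136 with an estimated correlation). The kinase gene PLK2 (1.75 ± 0.09), the BH3-only gene BBC3 (1.65 ± 0.12), FDXR (1.35 ± 0.13) and SESN2 (1.16 ± 0.14) were among those that rose. Of 18 pro-apoptotic genes, 9 rose and 0 fell (camera adjusted p = 0.0012, adjusted p = 0.136 with an estimated correlation), including BBC3 and a further BH3-only gene, BMF (1.14 ± 0.10). Of 10 anti-apoptotic genes, 6 fell and 2 rose (camera adjusted p = 0.0449, adjusted p = 0.205 with an estimated correlation), with BCL2 at -1.36 ± 0.07. That call was lost without DMSO replicate 1 (adjusted p = 0.0584) or CS2 replicate 1 (adjusted p = 0.0571), with camera alternatives ranging from 0.0351 to 0.205. The median log2 fold change of this list was -0.37, and -0.36 and -0.34 without these libraries. Of 21 interferon-stimulated genes, 15 rose and 3 fell (camera adjusted p = 4.32e-04, adjusted p = 0.136 with an estimated correlation), including IFI27 (2.75 ± 0.24), IFI35 (1.97 ± 0.15) and the transcription factor IRF7 (1.34 ± 0.15). Of 14 genes of MHC class I antigen presentation, 10 rose and 0 fell (camera adjusted p = 2.58e-05, adjusted p = 0.136 with an estimated correlation), among them the peptidase ERAP2 (1.63 ± 0.11) and the light chain B2M (1.20 ± 0.08). Of 21 autophagy and lysosome genes, 11 rose and 0 fell (camera adjusted p = 0.0012, adjusted p = 0.2 with an estimated correlation), led by the sialidase NEU1 (1.51 ± 0.12). Of 19 immediate early genes, 12 rose and 2 fell (camera adjusted p = 0.0112, adjusted p = 0.387 with an estimated correlation), with FOS at 1.72 ± 0.15 and ATF3 at 1.70 ± 0.13.

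Of 53 genes for cytosolic ribosomal proteins, 33 fell and 1 rose with CS2 (camera adjusted p = 1.71e-08, adjusted p = 0.387 with an estimated correlation). RPL23 (-1.32 ± 0.11) and RPL13A (-0.98 ± 0.08) had the largest declines among the examples. Of 13 mRNAs of the mitochondrial genome, 7 fell and 2 rose, and 8 fell when adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.655 with an estimated correlation), while the share of counts from mitochondrial ribosomal RNA was higher, as given above. Of 6 markers of tuft-like tumour cells, 3 fell and 0 rose, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0447, adjusted p = 0.2 with an estimated correlation), with SOX9, a transcription factor also found in other epithelia, at -0.94 ± 0.10. That call was lost without CS2 replicate 3 (adjusted p = 0.0525), with camera alternatives ranging from 0.0253 to 0.2, while the median of this list was -0.88 with and without that library. Of 29 integrated stress response genes, 13 rose and 7 fell, and 14 rose when adjusted over the list alone. The camera test of this list lay at the threshold (adjusted p = 0.05, adjusted p = 0.559 with an estimated correlation) and was lost without DMSO replicate 2 (0.0607), DMSO replicate 3 (0.062) or CS2 replicate 3 (0.0793), with camera alternatives ranging from 0.0152 to 0.559. It was also lost without mitochondrial genes (0.0505) and with the correction for GC content and span (0.153). The median log2 fold change of this list was 0.44, and under these alternatives, in the same order, it was 0.29, 0.30, 0.46, 0.44 and 0.38.

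The remaining lists did not pass camera with CS2. Higher and lower members numbered 10 and 8 of 23 neuroendocrine markers (9 lower adjusted over the list alone), 7 and 7 of 20 neuronal and synaptic genes, 7 and 4 of 18 NRF2 targets (5 lower adjusted over the list alone), 3 and 4 of 21 m6A writers, erasers and readers (2 higher adjusted over the list alone), 4 and 2 of 18 endoplasmic reticulum chaperone genes, 4 and 4 of 19 hypoxia genes and 1 and 2 of 40 nuclear-encoded respiratory chain genes (1 lower adjusted over the list alone). Members of the heat shock list were higher and lower in 7 and 2 of 15 genes, of the fatty acid synthesis list in 2 and 6 of 13, of the cholesterol synthesis list in 5 and 7 of 23, and of the glycolysis list in 4 and 7 of 20. In the list of ribosome biogenesis and other MYC-responsive genes they were so in 3 and 12 of 25 (13 lower adjusted over the list alone). The ribosome biogenesis list passed with the correction for GC content and span. They numbered 7 and 3 of 12 iron handling genes, 3 and 0 of 5 aryl hydrocarbon receptor targets, 3 and 6 of 18 Notch pathway genes and 5 and 4 of 10 nuclear long non-coding RNAs. Of markers of other cell states or types, 4 and 3 of 12 non-neuroendocrine, 2 and 2 of 10 fibroblast and 2 and 2 of 6 squamous and airway markers were higher and lower. The median, mean and test differed in sign for the hypoxia, nuclear long non-coding RNA and squamous lists. Of blood cell and endothelial markers only 4 and 3 genes were measured well enough to enter the test, fewer than the 5 required, so neither list was tested.

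The next comparison asked which transcripts differ between FB23-2 and DMSO. With FB23-2, 28 of 29 integrated stress response genes, targets of the transcription factor ATF4, rose, with a median log2 fold change of 1.55. Of further lists, 16 of 18 unfolded protein response genes (0 fell), 15 of 18 NRF2 targets (2 fell) and 8 of 12 iron handling genes (0 fell) rose, while 17 of 24 G2/M genes (0 rose), 12 of 18 Notch pathway genes (2 rose) and 13 of 23 neuroendocrine markers (5 rose) fell. Each of these lists passed camera and lost its call with an estimated correlation (adjusted p = 0.0601 to 0.302 with an estimated correlation), and that of the neuroendocrine markers was also lost with the correction for GC content and span. TRIB3, a pseudokinase induced by ATF4, rose 32-fold from 5.16 ± 0.78 to 166 ± 9.4 CPM (log2 fold change 5.0 ± 0.13, adjusted p = 1.46e-15). DDC, the aromatic amino acid decarboxylase, fell from 324 ± 17 to 53.7 ± 10 CPM (-2.59 ± 0.10, adjusted p = 2.23e-13). In all, 10290 genes passed, 5015 higher and 5275 lower, and 3254 of them differed by more than 2-fold, 1386 higher and 1868 lower.

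FTO was 58.3 ± 6.2 CPM with FB23-2 and 56.9 ± 1.6 with DMSO, and did not pass (log2 fold change 0.04 ± 0.09, adjusted p = 0.754). It passed only with the correction for GC content and span, at 0.22. MYCN fell from 1230 ± 35 to 904 ± 120 CPM (-0.44 ± 0.10, adjusted p = 8.37e-04). RARA, a retinoic acid receptor, fell by 0.50 on the log2 scale (± 0.14, adjusted p = 0.005), and CEBPA, at 0.855 CPM, rose by 2.09 ± 0.46 (adjusted p = 7.78e-04). DHODH was higher by 0.35 ± 0.12 (adjusted p = 0.0174), a call lost without DMSO replicate 1 (log2 fold change 0.32), DMSO replicate 2 (0.32) or FB23-2 replicate 1 (0.29). NEUROD1, a neuroendocrine transcription factor, was near the detection limit at 0.292 CPM and did not pass (-0.98 ± 0.42, adjusted p = 0.0556), but passed without DMSO replicate 1 (-1.17). ALKBH5 (0.02), METTL3 (0.09), METTL14 (0.19), MYC (0.37), PFKP (0.10) and LDHB (-0.35) did not pass, and of these PFKP passed with the correction for GC content and span, at 0.19.

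The largest increase was in LMX1A, a developmental transcription factor (35.2-fold, from 0.445 ± 0.048 to 15.8 ± 2.7 CPM). GDF15, a stress-induced cytokine, rose 27.4-fold to 101 ± 23 CPM. INHBE, an inhibin subunit gene, rose 18.7-fold, BEST1, a chloride channel gene, 16.6-fold, the AP-1 family gene JDP2 15.1-fold, PRR15 14.5-fold, and CHAC1, a glutathione-degrading enzyme gene, 13.1-fold. BEST1 shares 14.2% of its exon bases with the abundant gene FTH1. The largest decreases were in IGHM, the immunoglobulin mu heavy chain gene (45.8-fold, from 53.8 ± 2.3 to 1.18 ± 0.16 CPM), PERCC1 (43.4-fold), MUC5AC, a secreted airway mucin gene (40-fold), FAM30A (38.4-fold), C1orf127 (13.5-fold), MAB21L4 (13.3-fold), CCDC154 (13-fold) and FLI1, an ETS transcription factor gene (12.6-fold). All of these genes passed, with adjusted p up to 1.98e-07, that of FAM30A. IGHM and FAM30A lie near each other on chromosome 14, at 105851705 to 105856218 and 105917979 to 105932642. PERCC1 and CCDC154 are neighbours on chromosome 16, at 1431035 to 1433397 and 1434383 to 1444556.

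The integrated stress response list had 28 members higher and 0 lower of 29 (camera adjusted p = 4.20e-24, adjusted p = 0.0601 with an estimated correlation). PCK2 (2.77 ± 0.09), ATF3 (3.29 ± 0.13) and DDIT3 (2.52 ± 0.10), which shares 39.6% of its exon bases with other genes, were further members. Without FB23-2 replicate 2, whose mitochondrial share stood apart, 28 were higher and 0 lower. Of 18 endoplasmic reticulum chaperone and unfolded protein response genes, 16 rose and 0 fell (camera adjusted p = 3.33e-10, adjusted p = 0.0601 with an estimated correlation), led by HERPUD1 (1.87 ± 0.09) and SEL1L (1.43 ± 0.09), both of protein degradation at the endoplasmic reticulum. Of 18 NRF2 targets, 15 rose and 2 fell, and 16 rose when adjusted over the list alone (camera adjusted p = 3.93e-06, adjusted p = 0.15 with an estimated correlation). The cystine transporter gene SLC7A11 rose by 2.21 ± 0.11 and the aldo-keto reductase gene AKR1C3 by 2.18 ± 0.13. AKR1C1 (2.56 ± 0.13) and AKR1C2 (1.32 ± 0.11) share 28.7% and 52.2% of their 50-base windows with other genes, so their counts are uncertain. Of 12 iron handling genes, 8 rose and 0 fell (camera adjusted p = 0.00371, adjusted p = 0.15 with an estimated correlation), with the transferrin receptor gene TFRC at 1.64 ± 0.08. Of 19 hypoxia genes, 10 rose and 2 fell (camera adjusted p = 0.00371, adjusted p = 0.469 with an estimated correlation), with the prolyl hydroxylase gene P4HA2 at 2.72 ± 0.14. VEGFA, a member singled out after its values were seen, was at 32.95 CPM in DMSO replicate 1 against 8.587 and 6.817 in the other DMSO libraries, and without that library 12 hypoxia genes were higher and 1 lower. Of 5 aryl hydrocarbon receptor targets, 3 rose (camera adjusted p = 0.0273, adjusted p = 0.15 with an estimated correlation), including CYP1A1 (2.19 ± 0.22).

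Of 24 G2/M genes, 17 fell and 0 rose with FB23-2 (camera adjusted p = 4.42e-07, adjusted p = 0.15 with an estimated correlation). The mitotic genes PLK1 (-1.67 ± 0.08), CCNB1 (-1.52 ± 0.09), KIF20A (-1.40 ± 0.08) and AURKA (-1.31 ± 0.08) fell. Of 22 homologous recombination genes, 17 rose and 1 fell (camera adjusted p = 4.71e-06, adjusted p = 0.15 with an estimated correlation), with XRCC2 at 1.11 ± 0.09. Of 20 histone genes, 8 fell and 2 rose (camera adjusted p = 0.0311, adjusted p = 0.338 with an estimated correlation), a call lost without FB23-2 replicate 1 (adjusted p = 0.0748) and with the correction for GC content and span (adjusted p = 0.103), with camera alternatives ranging from 0.0107 to 0.338. The median log2 fold change of this list was -0.38, and -0.39 and -0.35 under these alternatives. Of 25 genes of ribosome biogenesis and other MYC-responsive genes, 13 fell and 2 rose (camera adjusted p = 0.00878, adjusted p = 0.15 with an estimated correlation), led by SRM, the spermidine synthase gene (-1.14 ± 0.08). Of 40 nuclear-encoded respiratory chain genes, 20 fell and 3 rose (camera adjusted p = 0.00956, adjusted p = 0.679 with an estimated correlation), among them ATP5MC1 (-0.71 ± 0.11). Without DMSO replicate 1, 14 of these fell.

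Of 23 neuroendocrine markers, 13 fell and 5 rose, and 14 fell when adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.161 with an estimated correlation). GRP, the gene of gastrin-releasing peptide, was at -1.99 ± 0.09 and TAGLN3 at -1.01 ± 0.07. The call of this list was lost with the correction for GC content and span (adjusted p = 0.122), which moved its median log2 fold change from -0.43 to -0.20, with camera alternatives ranging from 0.00451 to 0.161. Of 18 Notch pathway genes, 12 fell and 2 rose (camera adjusted p = 0.00169, adjusted p = 0.302 with an estimated correlation), with the receptor gene NOTCH1 at -2.31 ± 0.15 and the target gene HES1 at -2.19 ± 0.23. Of 6 squamous and airway epithelial markers, 6 fell (camera adjusted p = 0.00137, adjusted p = 0.15 with an estimated correlation), including MUC5AC, KRT15 (-2.43 ± 0.16), KRT7 (-2.36 ± 0.25) and FOXJ1 (-2.76 ± 0.39), and 5 fell without FB23-2 replicate 2. FOXJ1 was at only 0.941 ± 0.26 CPM with DMSO, so its fold change rests on few reads. Of 14 antigen presentation genes, 10 rose and 1 fell, and 11 rose when adjusted over the list alone (camera adjusted p = 3.98e-04, adjusted p = 0.15 with an estimated correlation), with ERAP2 at 1.35 ± 0.11 and the peptide transporter gene TAP1 at 1.27 ± 0.16. Of 10 nuclear long non-coding RNAs, 6 rose and 0 fell (camera adjusted p = 0.00858, adjusted p = 0.161 with an estimated correlation), with MALAT1 at 2.89 ± 0.23 and NEAT1 at 2.51 ± 0.35.

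The remaining lists did not pass camera with FB23-2. Higher and lower members numbered 16 and 2 of 53 ribosomal protein genes (12 higher adjusted over the list alone), 11 and 2 of 23 cholesterol synthesis genes (12 higher adjusted over the list alone), 8 and 7 of 26 G1/S genes, 7 and 4 of 24 p53 targets and 10 and 3 of 21 interferon-stimulated genes. The ribosomal protein and cholesterol lists passed without DMSO replicate 1 or FB23-2 replicate 2, the ribosomal protein list also without CS2 replicate 3 and with the correction for GC content and span, and the cholesterol list without FB23-2 replicate 1. Of mitochondrial mRNAs, 5 were higher and 2 lower of 13, and without FB23-2 replicate 2 these counts were 4 and 6. Higher and lower members numbered 6 and 9 of 20 neuronal and synaptic genes, 6 and 8 of 20 pyrimidine and deoxynucleotide synthesis genes, 5 and 6 of 13 fatty acid synthesis genes (6 higher adjusted over the list alone) and 6 and 3 of 19 immediate early genes. They numbered 9 and 7 of 18 pro-apoptotic genes, 2 and 5 of 10 anti-apoptotic genes, 9 and 4 of 21 autophagy and lysosome genes (5 lower adjusted over the list alone) and 0 and 3 of 6 tuft-like markers. The m6A list had 3 higher and 5 lower of 21 (4 lower adjusted over the list alone), the glycolysis list 5 and 7 of 20 (6 higher adjusted over the list alone) and the heat shock list 4 and 5 of 15. The non-neuroendocrine list had 4 and 3 of 12, the fibroblast list 3 and 2 of 10 (4 and 3 adjusted over the list alone). These last 5 lists had a median, mean and test that differed in sign.

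**Figure D3:**
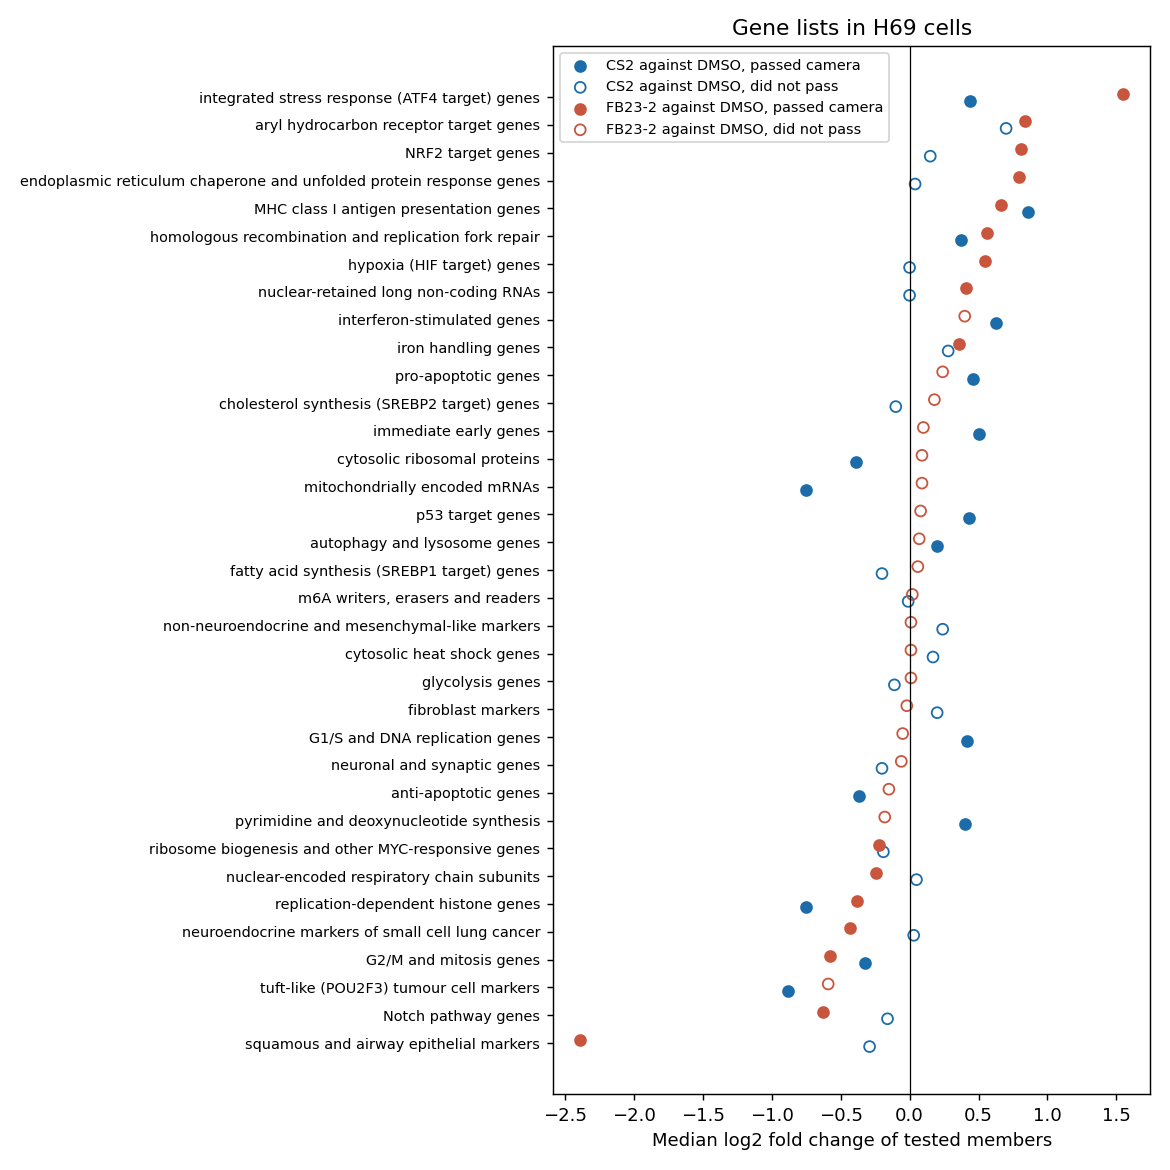
Median log2 fold change of the tested members of each gene list, with CS2 or FB23-2 against DMSO. Filled points passed camera at its preset correlation and open points did not, and 0 lists passed with an estimated correlation. The integrated stress response list had medians of 0.44 with CS2 and 1.55 with FB23-2, and the squamous list medians of -0.29 and -2.39.

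The last comparisons set the compounds against each other. With FB23-2, 28 of 29 integrated stress response genes (0 lower), 39 of 53 ribosomal protein genes (1 lower) and 15 of 18 unfolded protein response genes (0 lower) were higher than with CS2, while 20 of 26 G1/S genes (1 higher), 16 of 23 neuroendocrine markers (3 higher) and 11 of 21 interferon-stimulated genes (2 higher) were lower. Each of these lists passed camera and lost its call with an estimated correlation (adjusted p = 0.096 to 0.409 with an estimated correlation), and that of the interferon-stimulated genes was also lost with the correction for GC content and span. The test of FB23-2 against CS2 passed for 11799 genes, 5870 higher and 5929 lower with FB23-2, and 4561 of them differed by more than 2-fold, 2329 higher and 2232 lower. FTO was higher with FB23-2 than with CS2, by 0.55 ± 0.09 (adjusted p = 2.14e-05), but its direction turned to -0.16 with the correction for GC content and span (adjusted p = 0.0566; range over all alternatives 3.10e-08 to 0.755). DHODH was higher by 1.03 ± 0.12 (adjusted p = 5.99e-07). RARA was lower by a log2 difference of -0.51 ± 0.14 (adjusted p = 0.00364), a call lost with that correction (-0.15). PFKP was higher by 0.40 ± 0.09 (adjusted p = 0.00111). ALKBH5 was lower (-0.26 ± 0.09, adjusted p = 0.017), a call lost without CS2 replicate 2 (-0.25) or FB23-2 replicate 3 (-0.24) and with the correction for GC content and span (-0.05). METTL3 (-0.06), METTL14 (0.04), NEUROD1 (-0.62), MYCN (0.07), MYC (-0.06), CEBPA (-0.11) and LDHB (-0.05) did not pass, which does not show that their levels were alike. MYCN passed with the correction for GC content and span, at 0.38.

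AQP4, a water channel gene, was 37.4-fold higher with FB23-2 than with CS2, HS6ST3 21.6-fold, PRR15 19.2-fold, TRIB3 18.1-fold, the complement gene C5 17.5-fold and ENDOD1 14.9-fold. C1orf127 was 18.8-fold lower with FB23-2, the long non-coding RNA gene NBAT1 and MUC5AC each 18.2-fold, SLC18A1, a vesicular monoamine transporter gene, and IGHM each 10.6-fold, and the adaptor gene GRAP2 10.1-fold. All passed, with adjusted p up to 1.36e-09, that of AQP4.

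Of 29 integrated stress response genes, 28 were higher with FB23-2 and 0 lower (camera adjusted p = 1.56e-16, adjusted p = 0.096 with an estimated correlation), with MTHFD2, a mitochondrial folate enzyme gene that shares 33.2% of its exon bases with other genes, at 1.90 ± 0.08. Of 53 ribosomal protein genes, 39 were higher and 1 lower (camera adjusted p = 2.60e-09, adjusted p = 0.409 with an estimated correlation), with RPL13A at 1.29 ± 0.08. Of 18 unfolded protein response genes, 15 were higher and 0 lower (camera adjusted p = 9.54e-08, adjusted p = 0.096 with an estimated correlation), with the transcription factor gene XBP1 at 1.04 ± 0.08. Of 26 G1/S genes, 20 were lower and 1 higher, and 21 lower when adjusted over the list alone (camera adjusted p = 1.94e-06, adjusted p = 0.304 with an estimated correlation), with the cyclin gene CCNE1 at -1.68 ± 0.10. Of 20 pyrimidine and deoxynucleotide synthesis genes, 12 were lower and 1 higher (camera adjusted p = 0.00179, adjusted p = 0.096 with an estimated correlation), with UMPS, a pyrimidine synthesis enzyme gene, at -0.91 ± 0.11. Of 24 G2/M genes, 15 were lower and 3 higher, and 16 lower when adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.409 with an estimated correlation). Without FB23-2 replicate 2, 18 were lower and 1 higher. Of 20 histone genes, 10 were higher and 3 lower (camera adjusted p = 0.0333, adjusted p = 0.409 with an estimated correlation).

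Of 23 neuroendocrine markers, 16 were lower with FB23-2 than with CS2 and 3 higher (camera adjusted p = 9.80e-04, adjusted p = 0.145 with an estimated correlation), with GRP at -2.33 ± 0.09 and the granin gene CHGB at -1.07 ± 0.09. Of 18 Notch genes, 13 were lower and 2 higher (camera adjusted p = 0.00683, adjusted p = 0.409 with an estimated correlation), and of 6 squamous and airway markers 4 were lower (camera adjusted p = 0.00937, adjusted p = 0.177 with an estimated correlation). Of 21 interferon-stimulated genes, 11 were lower and 2 higher (camera adjusted p = 0.022, adjusted p = 0.304 with an estimated correlation), with CMPK2 at -2.31 ± 0.14. Of 18 NRF2 targets, 12 were higher and 4 lower (camera adjusted p = 0.00315, adjusted p = 0.409 with an estimated correlation). Of 13 mitochondrial mRNAs, 8 were higher and 1 lower (camera adjusted p = 0.00578, adjusted p = 0.544 with an estimated correlation), with MT-ND4 at 1.67 ± 0.21. Of 40 respiratory chain genes, 21 were lower and 4 higher (camera adjusted p = 0.00965, adjusted p = 0.6 with an estimated correlation). Of 10 RNAs listed as nuclear long non-coding RNAs, 6 were higher (camera adjusted p = 0.0151, adjusted p = 0.309 with an estimated correlation). The list member GAS5, which fell with CS2 against DMSO (-1.20 ± 0.08), was at 2.21 ± 0.08. Whether the listed RNAs are nuclear in these cells was not tested. Of 19 hypoxia genes, 11 were higher and 2 lower, and 12 higher when adjusted over the list alone (camera adjusted p = 0.0191, adjusted p = 0.544 with an estimated correlation). Of 23 cholesterol synthesis genes, 13 were higher and 2 lower (camera adjusted p = 0.0191, adjusted p = 0.544 with an estimated correlation), a call lost without FB23-2 replicate 3 (adjusted p = 0.103), with camera alternatives ranging from 0.00161 to 0.544. With the correction for GC content and span the calls of 4 lists were lost. Their median log2 fold changes went from -0.58 to -0.52 for interferon, from -0.26 to -0.21 for respiratory chain, from -0.83 to -0.32 for Notch and from 0.70 to 0.40 for nuclear long non-coding RNA genes. The remaining lists did not pass between the compounds, and of these the fatty acid synthesis list passed without FB23-2 replicate 2, with a median of 0.31 against 0.17. Higher and lower members with FB23-2 numbered 8 and 9 of 20 neuronal and synaptic genes, 6 and 10 of 24 p53 targets, 11 and 5 of 22 homologous recombination genes, 3 and 6 of 15 heat shock genes, 6 and 3 of 13 fatty acid synthesis genes, 7 and 7 of 20 glycolysis genes (9 and 8 adjusted over the list alone) and 7 and 3 of 12 iron handling genes. They numbered 1 and 7 of 14 antigen presentation genes, 3 and 0 of 5 aryl hydrocarbon receptor targets, 4 and 10 of 19 immediate early genes, 5 and 8 of 18 pro-apoptotic genes, 5 and 4 of 10 anti-apoptotic genes and 4 and 11 of 21 autophagy and lysosome genes. In the list of ribosome biogenesis and other MYC-responsive genes they numbered 4 and 10 of 25. The median, mean and test differed in sign for the fibroblast (3 and 4 of 10), tuft-like (0 and 1 of 6), m6A (3 and 5 of 21) and non-neuroendocrine lists (3 and 4 of 12, 2 higher adjusted over the list alone).

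Both compounds moved some genes in the same direction and others in opposite directions. LINGO3, a leucine-rich repeat protein gene, fell with both (-2.68 ± 0.12 with CS2, -2.74 ± 0.12 with FB23-2), as did NXPH1, a neurexophilin gene (-2.23 ± 0.16 and -2.18 ± 0.16), and FRMPD1 (-2.01 ± 0.15 and -2.04 ± 0.15). IGHM and FAM30A also fell with CS2, 4.33-fold and 4.13-fold. SDC3, a syndecan gene, rose with both (1.93 ± 0.11 and 2.22 ± 0.11). SLC7A11 fell with CS2 to 14.5 ± 1.6 CPM and rose with FB23-2 to 146 ± 16 CPM, from 31.6 ± 3.7 with DMSO. In all, 3972 genes were called in the same direction, 1945 higher and 2027 lower, where independent lists of these lengths would share 1221 and 1337. In 50 simulations of unchanged groups that share simulated controls, a mean of 0.12 genes and at most 1 were called in the same direction, and 0 in opposite directions. With no gene changed, the adjusted threshold lets almost no gene pass. These counts therefore do not measure what the shared controls add to the shared calls in the data. A further 1720 were called in opposite directions, 894 higher with CS2 and 826 higher with FB23-2, where independent lists would share 1284 and 1271.

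The log2 fold changes of the compounds against DMSO had a covariance of 0.235 across genes. In 50 simulations of unchanged groups that share simulated controls it was 0.0291, a difference of 0.205. Each draw was filtered anew, so its genes are not the same set as in the data. The covariance in the data was 0.152 with a mean of at least 1 CPM and 0.42 with DESeq2. It thus depends on the genes and method used, and 0.205 is not a measured size of the shared effect. Their Pearson correlation across genes was 0.288 (Spearman 0.272), below the 0.489 that the shared controls gave with no effect, and 58.9% of genes had the same sign against 66.5% in the simulations. In the simulations the correlation and the share of same signs come from error alone, so they are not levels for the data to exceed. Genes are not independent replicates. The 3 control libraries could not be split into subsets of 2 libraries each, so part of the excess in shared calls may come from the shared controls.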

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

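The genes in this part were chosen by a rule fixed in advance. Each was called in opposite directions by the compounds, with all 3 libraries of each treatment on its own side of DMSO. The difference between the effects of FB23-2 and CS2, from edgeR's fit, follows from that selection against the same DMSO libraries, so it is given as a size with its SE and not as a further test. SLC7A11, the cystine transporter gene, was at -1.12 ± 0.11 (SE) with CS2 and 2.21 ± 0.11 with FB23-2, a difference of 3.33 ± 0.11. CEP290, a ciliary protein gene, was at -1.62 ± 0.15 and 1.30 ± 0.14, a difference of 2.91 ± 0.15. PCLO, a gene of the presynaptic zone, was at -1.50 ± 0.10 and 1.19 ± 0.10, a difference of 2.69 ± 0.10. KIAA1958 was at -1.53 ± 0.11 and 1.15 ± 0.11, a difference of 2.67 ± 0.11. RNF150, a RING finger protein gene, was at -1.18 ± 0.12 and 1.13 ± 0.11, a difference of 2.31 ± 0.12.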

How the results depend on the processing

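The correction for GC content and gene span, the removal of mitochondrial genes and the list counts without FB23-2 replicate 2 or DMSO replicate 1 were chosen after seeing the data, as were both tests of the integrated stress response median. Counts of called genes stayed within 1.5 times the reported ones under the other settings run: leaving out single libraries gave 8345 to 11024 genes for CS2, 8795 to 10491 for FB23-2 and 10965 to 11848 between the compounds, and 3102 to 4464 genes called in the same direction by both. Against a 1.5-fold change (glmTreat), which asks for larger effects by construction, 3006, 3242 and 4904 genes passed. With an estimated correlation, camera called 0, 0 and 0 lists, and fry, which does not compare a list with other genes, called 28 between the compounds. Leaving out single libraries gave 14 to 16, 16 to 18 and 16 to 18 lists. With the replicate number as a block, 10271, 10698 and 12136 genes, 15, 16 and 17 lists and 4259 shared genes were called, and the tuft-like list with CS2 was lost. Deviations of same-numbered libraries of DMSO and a compound correlated from -0.03 to 0.02, which shows no pairing with the controls. Those of CS2 and FB23-2 correlated at 0.17, 0.12 and 0.05, above all differently numbered pairs of these groups (-0.14 to 0.02). A weak link between same-numbered libraries of the compounds is therefore not excluded. The offsets reversed 121 calls for CS2, 0 for FB23-2 and 112 between the compounds, and no other setting reversed a call. Of the named genes' values, 7132 kept their side and direction, 100 fell below the threshold (78 of them under glmTreat), 4 newly passed and 23 changed sign, and of the results for lists that passed 666 kept and 67 lost their call. The cause was not tested for any sign change. The offsets take out each library's trend with GC content and span, whether it is technical or an effect of the compound. With CS2, FTO was at -0.52 and genes spanning 200 to 500 kb had a median of -0.57. The value of FTO with the offsets is thus relative to genes of like span and GC content. With the offsets, FTO came to 0.38 with CS2 and -0.16 between the compounds, RARA to -0.18 with CS2, METTL3 to -0.02 and METTL14 to -0.05 with FB23-2, and METTL14 to -0.13, MYC to 0.17, CEBPA to 0.40 and SNHG14 to -0.04 between the compounds. Leaving out single libraries, values ranged from -0.08 (without CS2 replicate 1; 0.00 without DMSO replicate 1) to 0.07 for RARA with CS2, and with FB23-2 from -0.05 (without FB23-2 replicate 2) to 0.10 for FTO and from -0.05 (without DMSO replicate 2) to 0.11 for ALKBH5. Between the compounds they ranged from -0.12 to 0.00 (without FB23-2 replicate 2) for METTL3, from -0.08 (without FB23-2 replicate 2; 0.00 without CS2 replicate 1) to 0.11 for METTL14, and from -0.02 (without FB23-2 replicate 2) to 0.19 for MYCN. They ranged from -0.23 to 0.26 for MYC (0.26 without CS2 replicate 1, 0.11 without FB23-2 replicate 3), from -0.37 to 0.21 for CEBPA (0.21 without FB23-2 replicate 1, 0.19 without CS2 replicate 1) and from -0.18 to 0.15 for LDHB (0.15 without CS2 replicate 3, 0.13 without FB23-2 replicate 2). The median of the integrated stress response list with FB23-2, 1.55 as reported, was 1.59 with the offsets and 1.53 without FB23-2 replicate 2. The real split of the 6 libraries gave 10735 genes for CS2, 10055 for FB23-2 and 10915 between the compounds by edgeR, and the highest of the other splits gave 0 (171, 244 and 277 genes at an unadjusted p under 0.05, against 11552, 11129 and 11680). In each comparison 1 split, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so a difference between the groups adds to its spread and lowers its count. The counts of 0 therefore do not decide whether the calls arose by chance. Depth limits genes near the floor of 3 counts, such as NEUROD1, CEBPA and FOXJ1.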

Other observations

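The tests of transcript length and GC content for long genes, and of mitochondrial RNA, were chosen only after the result was seen, while the other tests of this part had their outcomes stated before they were run. Beyond the lists in the report, translation factors whose mRNAs carry a terminal oligopyrimidine tract, the motif shared with ribosomal protein mRNAs, formed a list made after the ribosomal protein result but before their own values were seen. Its p-values were adjusted together with the 35 lists of the same comparison, and it did not pass in any comparison with an estimated correlation. With CS2, 16 of 19 fell and 0 rose by edgeR, with a median log2 fold change of -0.50 (camera adjusted p = 1.33e-06, adjusted p = 0.123 with an estimated correlation). With FB23-2, 12 rose and 1 fell, with a median of 0.28 (camera adjusted p = 0.00781, adjusted p = 0.328 with an estimated correlation), and between the compounds 14 were higher and 1 lower with FB23-2, with a median of 0.88 (camera adjusted p = 7.36e-08, adjusted p = 0.148 with an estimated correlation). A candidate explanation for the lower ribosomal protein mRNAs with CS2 is a change of this mRNA class as a whole.

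Protein-coding genes spanning over 500 kb were lower with CS2. Their medians relative to genes spanning up to 50 kb were -1.60, -1.52 and -1.45 in the 3 libraries. These values were -0.08 to 0.05 in the DMSO libraries and -0.31, -0.08 and -0.35 with FB23-2. Transcript length, exon length and GC content do not account for all of it. The rank correlation of the fold change with span across genes was -0.323, and -0.221 (SD 0.0098 over resampled genes) at fixed values of these. At fixed span and GC content that with transcript length was -0.042, and at fixed span and transcript length that with GC content was 0.072. Because these traits may vary together with span, the drop from -0.323 does not show that they account for a part. An even background of genomic DNA in the DMSO libraries is argued against. The 10th percentile of the DMSO level in all 317 protein-coding genes over 500 kb, tested or not, was 0.0964 CPM per Mb. That is a ratio of 0.00359 to the median loss of 26.8 CPM per Mb in the 203 called lower. More intron reads of transcribed genes in the DMSO libraries stay open, because genes with so few reads cannot show them. Neither was the decrease with span a loss of neuronal and neuroendocrine expression alone. In this test long members of those lists spanned over 100 kb, not 500 kb, and short ones under 50 kb. The long ones lay -0.90 below the short ones (11 long, median -0.62, and 28 short, median 0.28, permutation p = 1.10e-04). An effect of the CS2 treatment itself stays open and was not tested, and gene counts do not show where along a gene its reads lie. FTO, at 456.8 kb, is not in the class over 500 kb.

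With CS2, the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 rose by 2.24 ± 0.18 and 2.04 ± 0.28, while 7 of 13 mitochondrial mRNAs fell and 2 rose. These counts are the pattern itself and no separate test of it, and they only say that mitochondrial RNA was not higher in every kind. The mRNAs called neither way numbered 4. Unequal capture of mitochondrial transcripts in the poly(A) step, which gene counts do not show, cannot be told apart from a change in the cells, because no value here measures tails or capture.

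Genes that fell by more than 4-fold often lay next to other genes that fell. Of 524 such genes with FB23-2, 212 (40.5%) had a neighbour without shared exon bases that was lower by more than 2-fold, against 78.4 (15%) with shuffled positions (permutation p = 0.0001, the smallest that 10000 shuffles can give). With CS2, 141 of 498 did (28.3%), against 75.1 (15.1%, permutation p = 0.0001, again the smallest). GC content, span and overlap do not account for it alone: among non-overlapping protein-coding genes, corrected for GC content and span, 75 of 254 with FB23-2 (29.5%, shuffled 11.1%, permutation p = 0.0001) and 23 of 148 with CS2 (15.5%, shuffled 8.92%, permutation p = 0.011) had such a neighbour. A joint loss of expression over neighbouring genes is a candidate explanation, while neighbours that share a function or descend from a duplication, and transcripts that run on into the next gene, stay open and were not tested.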
